A study of Ovis aries with 2 samples.

How the data were processed

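RNA from the subcutaneous fat of sheep was sequenced in 2 libraries, 1 read from the labels as thin-tailed and 1 as fat-tailed, both from Iranian native breeds. Per the labels, the lambs were weaned at 90 days, received the same feed for 120 days without restriction and were slaughtered at 7 months. Total RNA was extracted with TRIzol and poly(A) RNA was made into Illumina libraries, per the labels' protocols. The fat-tailed library was assigned from its title, which differs from that of the other library in this word alone, and from the series' stated contrast of tail types. The source label names subcutaneous fat in the same words for both libraries, so the word Fat in that title could also name the tissue. This reading sets the direction of every difference. The series text speaks of duplicates, and 1 library per tail type was analysed here. Whether a library holds RNA of 1 animal or a pool is not given in the sources used here.

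The deposited values are FPKM, that is, mapped fragments scaled to transcript length and to the mapped fragments of the library, with a lower and an upper bound for each value. The column names are those of a Cufflinks or Cuffdiff tracking table, per the file headers, and FastQC, TopHat and Cuffdiff are listed, without version or order, per the submitters' processing notes. The genome build, the annotation release and any scaling between the libraries are not given in the sources used here. Positions are therefore printed as deposited, counted from 1, with no build named. Loci carry either a name specific to 1 library, which marks an assembly made per library, or an Ensembl sheep gene identifier. The thin-tailed table held 34927 loci, 20562 of them assembled and 14365 with an Ensembl identifier. The fat-tailed table held 36511 loci, 21241 assembled and 15270 with an Ensembl identifier. Of the loci with an Ensembl identifier, 78.7% in the thin-tailed and 77.6% in the fat-tailed library were listed at 0, against 4.25% and 4.33% of the assembled loci. A 0 in such a table can be a failed estimate or the result of fragments being given to an overlapping locus, so it is reported as listed at 0. Every locus had the status OK.

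Gene names were absent from both tables. None of the 14363 and 15268 distinct Ensembl identifiers occurred in the RefSeq gene table used (assembly ARS-UI_Ramb_v3.0), so nuclear loci are described by position and gene names are not used for them. Mitochondrial loci were the exception: 33 loci of the thin-tailed and 31 of the fat-tailed table had exactly the start and end of 1 of the 37 mitochondrial genes in that table, and 2 loci in each had the outer ends of 2 overlapping genes. These loci took the names of those genes. Of the 35 gene lists set before the data were examined, only that of the mitochondrially encoded genes could be measured; the other 34 lists, which need nuclear gene names, were not analysed. The rule set beforehand for naming genes also needs names. In its place, up to 2 Ensembl identifiers per direction were printed by a rule chosen after the data were seen. It took the highest and the lowest ratios among loci on assembled chromosomes with a span of at least 1000 bp, an Ensembl identifier in at least 1 table and at least 5 FPKM in 1 library. It also required values above 0 in both libraries, no overlap with another locus of the same table, deposited intervals that did not overlap, and implied fragment numbers (below) differing 2-fold the same way. The same rule with at least 100 FPKM and no identifier required gave the abundant loci named by position.

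Because the assemblies were separate, loci were matched between the tables by position, a step added once the tables had been seen. A pair was kept when each locus was the other's best partner and the overlap covered at least 80% of both. Pairs with tied partners, 70 in all, were left out. This gave 28180 pairs, 80.7% of the thin-tailed and 77.2% of the fat-tailed loci, and 17258 of the pairs had identical ends. The tables give no strand, so loci that overlap on opposite strands could share fragments. Pairs with FPKM of at least 1 in at least 1 library, 13120 in all, were compared as log2((fat-tailed FPKM + 1)/(thin-tailed FPKM + 1)), a scale that understates the ratios of low values. Loci at 1 or above, or at -1 or below, were counted as 2-fold higher or lower. With 1 library per tail type there is no replicate check, no p-value was computed, and every difference is one between these libraries. The median ratio of the mitochondrial genes, of each chromosome with at least 100 compared loci and of each 1 Mb window with at least 8 was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. The chromosomes and windows were added after the data were seen, as were lists for them matched on decile of span and on 5 bins of expression. A median stood apart when it lay outside the central 95% of the random medians. The random lists came from all 13120 loci in place of loci with names.

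Fragment counts were not used here, but the width of an interval holds a trace of them. If the bounds lie 2 standard deviations from the value and counting error alone sets that width, the number of fragments behind a locus can be computed. Among loci with implied numbers of up to 20, 61.0% in the thin-tailed and 60.5% in the fat-tailed library came within 0.02 of a whole number, where 4% would by chance. Across 1501 loci with identical ends and such whole numbers in both libraries, the FPKM value of 1 fragment gave a fat-tailed depth of 0.973 times the thin-tailed depth (quartiles 0.951 and 0.997). Any scaling between the libraries, which is not given, would enter this estimate. Ratios of implied fragments were divided by this estimate of relative depth. For loci with several transcripts, or where more than counting error sets the width, the implied number is only approximate. Implied fragments come from the same estimates as the FPKM and are no independent check of them. The total depth is unknown. The intervals cover the uncertainty of the estimate within a library, not the variation between animals.

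Alternatives set before the data were examined changed the pseudocount (0.1 or 5), the minimum FPKM, the scaling (median ratio, total FPKM, upper quartile), the 2-fold threshold and the statistic of the list, or required status OK or intervals that did not overlap. Further alternatives, chosen after the data were seen, changed the matching overlap, the scaling and the kinds of loci used, or required support from implied fragments. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. The calls were tested on simulated data for the comparison of the libraries, with counting error only, over 13120 loci of which 200 were changed. The changed loci were drawn only from those with a mean of at least 5 FPKM and at least 20 implied fragments in the thin-tailed library. Of these changed loci 32.0% were recovered when the simulated change was 2-fold, 100% at 4-fold and 100% at 8-fold. Recovery among loci below those limits was not simulated. Of the unchanged loci 1.42% to 1.64% were called. Of 400 random lists of 10 of these loci, 4.50% stood apart with no shift and 39.0% with a shift of -0.5. In a matching test, 3000 thin-tailed loci were matched to copies of themselves with 1 end moved, by less than the overlap limit allows. Of these, 99.97% were paired, 99.97% of the pairs with the locus itself. High recovery was thus built in, and the test does not show how well loci of separate assemblies were matched.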

Results

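Transcript levels in subcutaneous fat were compared between 1 thin-tailed and 1 fat-tailed sheep, or pool of sheep, of Iranian native breeds at 7 months of age. Fat-tailed sheep store fat in the tail, and the series asked how the adipose transcriptomes of the tail types differ. Poly(A) RNA sequencing had been summarised by the authors as FPKM per locus. FPKM of at least 1 was listed for 19168 loci in the thin-tailed and 19865 in the fat-tailed library, and at least 100 for 1635 and 1611. The total depth is unknown. The fat-tailed depth came to 0.973 times the thin-tailed one, from the deposited intervals of loci with few fragments. That estimate holds only if no scaling between the libraries was applied. The median locus above 0 rested on 56.0 implied fragments in the thin-tailed and 47.5 in the fat-tailed library. The direction of every difference rests on reading the word Fat in 1 title as the tail type. Each tail type had 1 library, so no difference below has a replicate check, and bracketed ranges are the deposited intervals.

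The mitochondrial genes were the only ones that could be followed by name, and both ribosomal RNAs were higher in the fat-tailed library while most coding loci were lower. The large-subunit ribosomal RNA (MT 1094 to 2667), a structural RNA of the mitochondrial ribosome, stood at 64.0 FPKM (60.5 to 67.4) in the thin-tailed and 727.1 (715.5 to 738.8) in the fat-tailed library, an 11.4-fold difference. The small-subunit ribosomal RNA (MT 69 to 1026) stood at 19.0 FPKM (16.4 to 21.7) and 78.1 (72.8 to 83.3), 4.10-fold higher in the fat-tailed library. Implied fragment numbers differed in the same direction, with log2 ratios of 3.54 and 2.13. They come from the same estimates as the FPKM, so they are no independent evidence.

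Of the 10 loci holding 12 of the 13 mitochondrial coding genes, 8 had lower and 2 had higher FPKM in the fat-tailed library; centred on the median of all loci, COX3 turned higher, at a log2 ratio of 0.04. Among the genes for complex I, the entry point of electrons from NADH into the respiratory chain, the joint locus of ND4L and ND4 (MT 9885 to 11552) read 1514 FPKM (1448 to 1580) in the thin-tailed and 665.6 (634.9 to 696.3) in the fat-tailed library. Its log2 ratio was -1.18 by FPKM and -0.14 by implied fragments. ND6 (MT 13558 to 14085) read 2055 and 1036 FPKM, ND2 (MT 3910 to 4951) 268 and 170.3, and ND5 (MT 11754 to 13574) 226 and 193 in the thin-tailed and fat-tailed library. ND5 and ND6 overlap at their ends, and without strand their fragments could not be told apart there. The locus holding CYTB began at 13946 in the fat-tailed library, inside ND6, and at 14159 in the thin-tailed library, beyond ND6. Fragments of ND6 could thus be shared with that locus in the fat-tailed library only. ND1 (MT 2745 to 3699) read 50.4 FPKM (45.7 to 55.0) and 60.3 (55.1 to 65.4), and ND3 (MT 9469 to 9814) 3523 and 3816, both higher in the fat-tailed library. For cytochrome c oxidase, the last enzyme of the chain, COX1 (MT 5332 to 6876) read 1339 and 899 FPKM, COX2 (MT 7019 to 7702) 1363 and 1029, and COX3 (MT 8616 to 9399) 4596 and 4336 in the thin-tailed and fat-tailed library. The joint locus of ATP8 and ATP6 (MT 7775 to 8614), subunits of ATP synthase, read 2151 and 1122 FPKM.

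The deposited intervals of all 10 coding loci did not overlap between the libraries. Their median log2 ratio was -0.49 and lay at percentile 9.45 of the random lists, so the coding genes as a group did not stand apart from other loci of like expression. For COX1, ND5, ND6 and both joint loci the implied fragment ratios lay between -0.30 and -0.02 on the log2 scale. These loci had wide intervals for their FPKM. In the thin-tailed library COX1 (1545 bp) gave 2143 implied fragments at 1339 FPKM, and ND4L/ND4 (1668 bp) gave 2122 at 1514. The shorter COX2 (684 bp) gave 7708 at 1363 FPKM. Counting error alone thus did not set such widths, and implied fragments cannot check the FPKM ratios of these loci. CYTB, of complex III, was read alone in the thin-tailed library (MT 14159 to 15298) at 4098 FPKM, and within a longer locus (MT 13946 to 15960) at 1475 FPKM in the fat-tailed library, so it was not compared. All 21 matched loci of mitochondrial transfer RNAs were listed at 0 in both libraries. When FPKM totals were equalised, the median of all loci moved to -2.28. ND1, ND3 and the small ribosomal RNA changed direction, and relative to that median they stood at -0.48, -0.80 and 1.21. As deposited they stood 0.37, 0.24 and 2.10 above the median of all loci. Loci shorter than 200 bp held 94.2% of the thin-tailed and 99.4% of the fat-tailed total. The scaling is a log2 shift of -3.19, and the added 1 FPKM kept low values from moving by as much.

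**Figure D1:**
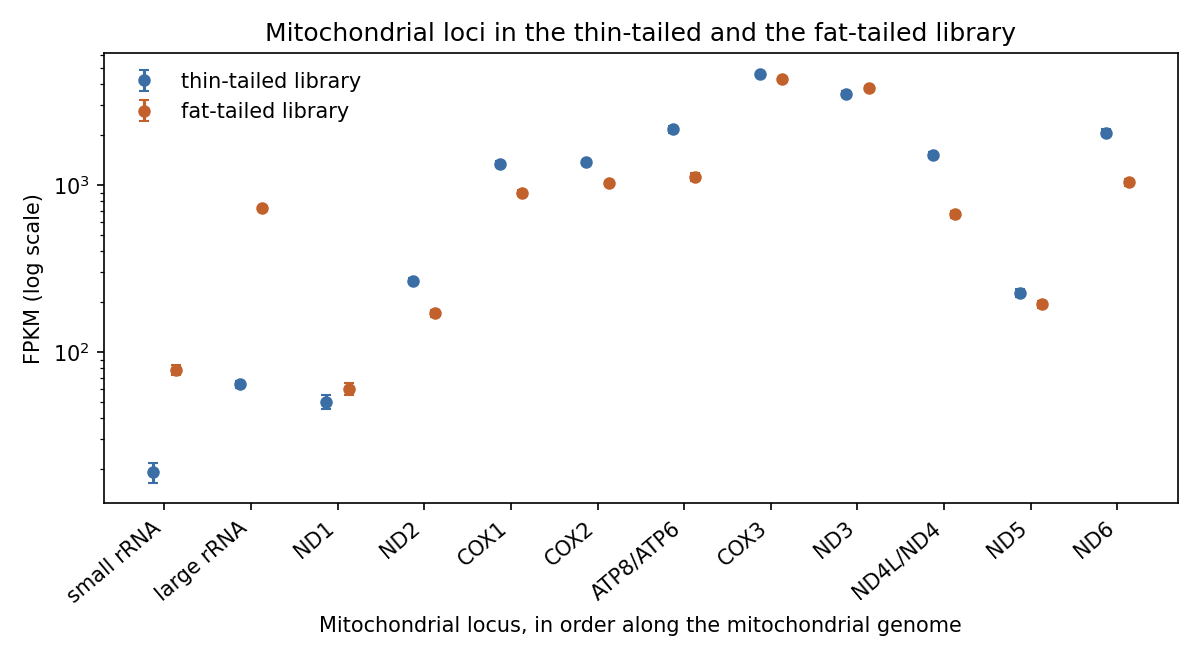
FPKM (log axis) of the 12 named mitochondrial loci, in genome order, in the thin-tailed (blue) and the fat-tailed library (orange), 1 library each; bars are the deposited intervals, often smaller than the points. The large ribosomal RNA stands at 64.0 in the thin-tailed and 727.1 in the fat-tailed library. In the fat-tailed library 8 of the 10 coding loci are lower. Centred on the median of all loci, COX3 is higher. With FPKM totals equalised, the small ribosomal RNA, ND1 and ND3 are lower too. Nearly all of those totals lies in loci shorter than 200 bp.

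Across all matched loci, 1089 were at least 2-fold higher and 1932 at least 2-fold lower in the fat-tailed library, or 8.30% and 14.7% of 13120. The remaining 10099 loci, 77.0%, lay within 2-fold. Differences of at least 8-fold were found for 91 higher and 123 lower loci. The median log2 ratio was -0.12, with quartiles at -0.63 and 0.36. Across loci, which are not independent replicates, log2 values of the libraries had a Pearson correlation of 0.895 and FPKM a Spearman correlation of 0.866.

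Of the called loci, 1003 of the higher and 1786 of the lower ones had intervals that did not overlap. Implied fragments could be computed for 948 of the higher and 1688 of the lower loci, the others being listed at 0 in 1 library. They differed in the same direction for 73.6% and 88.3% of these, and by at least 2-fold for 468 (49.4%) and 1149 (68.1%). Among the loci that overlapped no other locus, 592 were higher and 1174 lower. Higher loci made up 36.0% of the calls, and 0.388% when the libraries were scaled to the same total of FPKM, a total of which loci shorter than 200 bp held 94.2% in the thin-tailed and 99.4% in the fat-tailed library.

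**Figure D2:**
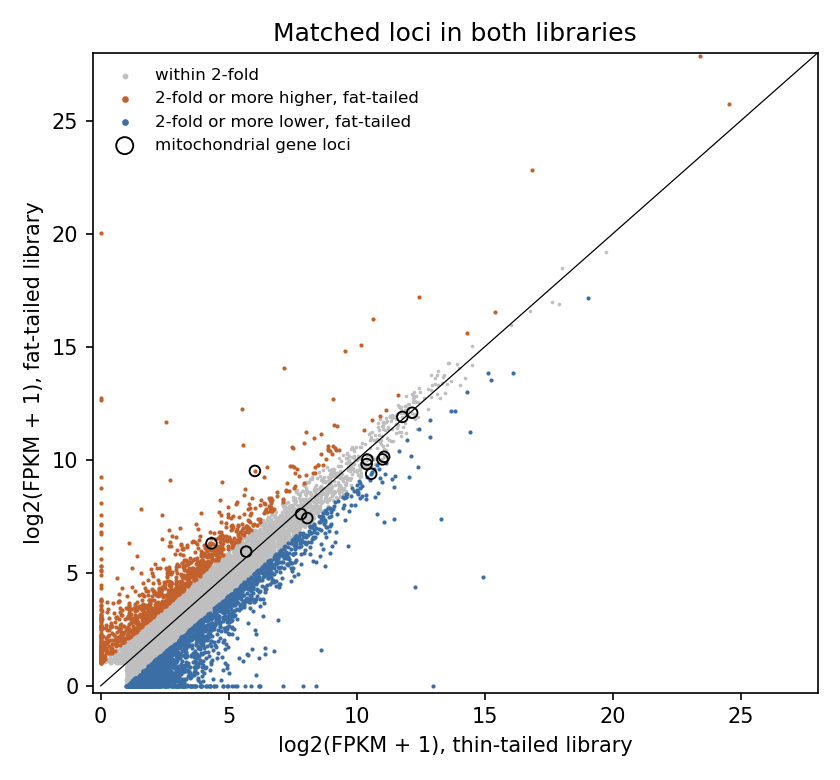
Each point is 1 of 13120 matched loci, with log2(FPKM + 1) in the thin-tailed library on the x axis and in the fat-tailed library on the y axis, 1 library each; the line marks equal values, orange and blue mark loci at least 2-fold higher and lower in the fat-tailed library, and open circles mark the named mitochondrial loci. The blue loci (1932) outnumber the orange ones (1089), and the points along the axes are listed at 0 in 1 library.

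Among loci with an Ensembl identifier, 4 named ones differed by 10.9-fold or more. ENSOARG00000007060 (chromosome 17, 8827171 to 8918625) read 1.65 FPKM (1.05 to 2.26) in the thin-tailed and 52.6 (47.8 to 57.3) in the fat-tailed library, a 31.8-fold difference (16.5-fold by implied fragments). ENSOARG00000004573 (chromosome 14, 800006 to 876421) read 4.39 FPKM (3.34 to 5.44) and 48.0 (40.8 to 55.1), 10.9-fold higher in the fat-tailed library, but only 2.66-fold by implied fragments. In the other direction, ENSOARG00000008480 (chromosome 11, 26321704 to 26328096) read 25.1 FPKM (22.9 to 27.3) in the thin-tailed and 0.201 (0 to 0.433) in the fat-tailed library. The latter value rested on 3 implied fragments, against 521 in the thin-tailed library. ENSOARG00000020789 (chromosome 3, 59304260 to 59314906) read 46.5 FPKM (37.9 to 55.1) and 1.16 (0.212 to 2.10), 40.2-fold lower in the fat-tailed library, on 117 and 6 implied fragments, or 19.0-fold by fragments. In all 4 cases the table with the lower value carried the identifier, and the other held an assembled locus, with a reciprocal overlap of at least 87.1%. The rule that picked these loci required a difference, so they show extremes and not how often loci differed.

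In the decile of loci with the highest mean level, 105 of 1312 loci were 2-fold higher and 193 lower in the fat-tailed library. The following loci were the highest and lowest ratios among those with at least 100 FPKM in 1 library that met the same conditions. A locus on chromosome 3 (100723193 to 100724856) read 179.0 FPKM (164.6 to 193.5) in the thin-tailed and 1478 (1414 to 1542) in the fat-tailed library, 8.25-fold by FPKM and 3.59-fold by implied fragments. On chromosome 1, the locus from 86230621 to 86238111 read 83.2 FPKM (72.4 to 93.9) and 603.4 (575.1 to 631.7), 7.26-fold by FPKM and 7.76-fold by fragments. Lower in the fat-tailed library were a locus on chromosome 6 (15304480 to 15444246), at 185.3 FPKM (179.2 to 191.5) against 28.1 (26.7 to 29.5), and one on chromosome 12 (69062808 to 69069280), at 125.5 (117.8 to 133.1) against 19.7 (17.2 to 22.3). These were 6.59-fold and 6.35-fold differences by FPKM, and 2.22-fold and 4.56-fold by fragments. The chromosome 3 locus had identical ends in both libraries, yet gave 614 implied fragments at 179.0 FPKM and 2145 at 1478. More than counting error may thus have set its interval widths. Fragment folds cannot check the FPKM folds of such loci. With FPKM totals equalised both higher loci changed direction, to log2 ratios of -0.15 and -0.33, and stood 2.13 and 1.95 above the median of all loci.

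Long loci were lower in the fat-tailed library more often than short ones. In the shortest decile of loci, with spans of 67 to 764 bp, the median log2 ratio was 0.09, and 10.5% were 2-fold higher against 11.3% lower. In the longest decile, from 94073 to 1040071 bp, the median was -0.32, and 8.54% were higher against 23.8% lower. The Spearman correlation of the ratio with span was -0.18 across loci.

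**Figure D3:**
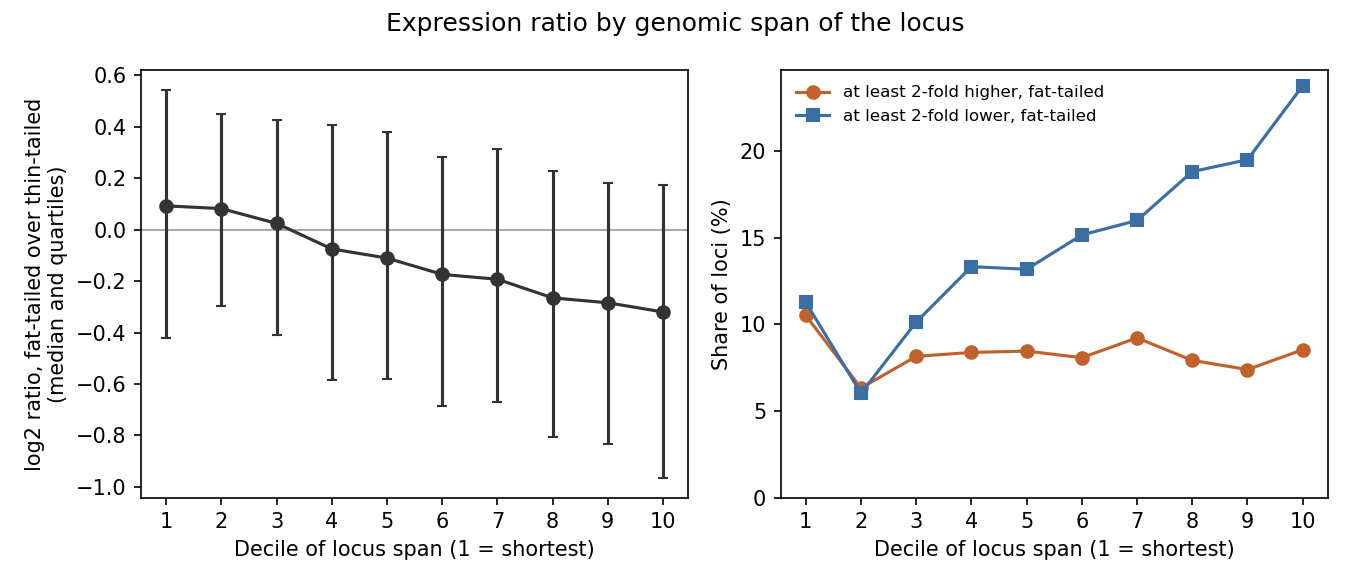
Log2 ratio of fat-tailed over thin-tailed FPKM (left, median as points and quartiles as bars) and the share of loci at least 2-fold higher (orange) or lower (blue) in the fat-tailed library (right, in percent), by decile of locus span, with 1312 loci in each and 1 library per tail type. The median goes from 0.09 in the shortest to -0.32 in the longest decile, and the share of lower loci from 11.3% to 23.8%.

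By chromosome, chromosomes 14 and 11 stood above the random lists, with median log2 ratios of 0.01 over 686 loci and -0.03 over 760 loci. Chromosomes 1 and 2 stood below them, with medians of -0.18 over 1177 and -0.19 over 982 loci. The other chromosomes, of 27 examined, did not stand apart. Across the 27 chromosomes, the Spearman correlation of the median ratio with the median span was -0.50. The median span was 8871 bp on chromosome 14 and 9554.5 bp on 11, against 16138 bp on 1 and 16725.5 bp on 2. Chromosomes X and 24, at 8455 and 7458 bp, had short loci without high medians, and chromosome 23, at 21648.5 bp, had long loci and a median of -0.06. Against lists matched on span as well, chromosomes 14, 11 and 2 stood apart, at percentiles 99.96, 98.9 and 1.98, and chromosome 1 did not, at 2.63. Chromosome X had 22 higher and 72 lower loci among 456, and its median of -0.17 lay at percentile 13.3, or 3.30 with span matched.

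Of 524 windows of 1 Mb, 23 stood above and 11 below the random lists, where 13.1 would in each direction by chance if loci were independent. Loci of a window can overlap and share fragments, and the lists behind these counts were not matched on span. The 13.1 is thus only a rough guide. The window on chromosome 13 from 66000001 to 67000000 had a median log2 ratio of 0.94 over 13 loci, 5 of them 2-fold higher and 2 lower, and that on chromosome 20 from 29000001 to 30000000 had 0.76 over 15 loci, 4 higher and 1 lower. Over loci that overlap no other the medians were 0.41 and 0.80, and by implied fragments 0.28 and 0.45. With FPKM totals equalised both medians were below 0, and 0.56 and 0.81 above the median of all loci. Most of the calls in the chromosome 20 window rested on values listed at 0. The higher loci starting at 29016884, 29942412 and 29991234 were at 0 in the thin-tailed library. The lower locus, starting at 29980761, was at 0 in the fat-tailed library. Farthest below the random lists were a window on chromosome 25 (28000001 to 29000000), with a median of -1.20 and 5 of 8 loci 2-fold lower, and one on chromosome 12 (2000001 to 3000000), with -0.99 and 6 of 13 loci lower. By implied fragments their medians were -0.52 and -1.12, with 6 of 8 and 6 of 11 loci lower. No locus in either of these was 2-fold higher; with FPKM totals equalised, the window on chromosome 12 stood 0.14 above the median of all loci. The windows were named after their values were seen, as those farthest outside the random lists.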

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

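Some loci lay outside every comparison because only 1 of the tables listed a locus at their position. Absence from the other table does not show that the other library lacked the transcript. Further loci overlapped one of the other table without forming a matched pair, and these were not compared either. In the thin-tailed library 1209 loci overlapped no locus of the fat-tailed table, and the deposited interval of all 1209 lay above 0. In the fat-tailed library 1460 loci overlapped none of the thin-tailed table, and the interval of 1459 lay above 0. None carried an Ensembl identifier. Their median span was 860 bp in the thin-tailed and 741.5 bp in the fat-tailed library, against 6572 and 4340 bp for all loci above 0. Their median FPKM was 2.45 (quartiles 1.71 and 3.998) and 3.14 (2.22 and 5.22). Of these loci, 15 in the thin-tailed and 18 in the fat-tailed library had at least 10 FPKM and a span of at least 1000 bp. No explanation of them was tested.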

How the results depend on the processing

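No paired analysis was possible because each tail type had 1 library and no test was made. The alternatives on matching, overlap, span, values above 0, the total of longer loci, the median of all compared loci and implied fragments were chosen after the data were seen. Lower loci outnumbered higher ones under all 18 alternatives to the counts. From 1089 higher and 1932 lower loci, the counts moved by over 1.5 times under 5 of them: to 598 and 893 with a pseudocount of 5, to 275 and 489 at 4-fold, to 592 and 1174 for loci that overlap no other, to 468 and 1149 when implied fragments also had to differ 2-fold the same way, and to 47 and 12066 with equal FPKM totals. The last follows from its construction: the fat-tailed total was 9.15 times the thin-tailed one, nearly all of it in loci shorter than 200 bp, and without these the counts were 1050 and 2003. The 4-fold threshold, the fragment condition and the restriction to 8289 loci that overlap no other select fewer loci by construction; a larger pseudocount draws every ratio towards equality. Omitting the filter on low values changed neither count, since the pseudocount already keeps loci below 1 FPKM from reaching 2-fold. It raised the compared loci from 13120 to 16870. Requiring status OK removed no locus. The median of the mitochondrial coding genes lay below 0 and inside the random lists under all 16 of its alternatives, at percentiles from 7.50 to 23.6. Of these, 7 kept the same loci and so the same median, centring cannot move a percentile, and only 39.0% of simulated lists of 10 loci with a shift of -0.5 stood apart. The median ranged from -3.67 with equal FPKM totals to -0.37. Depth limits the precision of each value: the median half-width of an interval was 26.7% of the FPKM in the thin-tailed and 29.0% in the fat-tailed library.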

Other observations

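The tests of overlapping loci, of both explanations of the mitochondrial pattern, and of scaling, low values and the span trend as sources of the uneven calls were chosen after the result was seen. The others were set before.

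Mitochondrial ribosomal RNA was 11.4-fold and 4.10-fold higher in the fat-tailed library. More mitochondrial RNA of every kind would raise the coding loci as well, and their median log2 ratio was -0.49, and the highest coding locus, ND1, stood at 0.254. The assembly placed the ribosomal loci and 6 coding loci under 1 identifier. An effect raising all loci of that identifier alike would raise those 6, and their median was also -0.49. This argues against such an even effect only. Whether the assembly changed the loci of that identifier unevenly was not tested and stays open. A different carry-over of ribosomal RNA through poly(A) selection stays open, as does a difference between the tail types; neither was tested, and with 1 library each they are confounded.

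The ratio of fat-tailed to thin-tailed FPKM fell with locus span. The level of expression did not account for all of it: within deciles of mean level the Spearman correlation was below -0.05 in 9 of 10. Its median within those deciles was -0.13, and -0.03 in the weakest, against -0.18 over all loci. Part of the trend could therefore go with level. Loci that overlap no other locus gave -0.19, which argues against overlaps between loci. The ratio of implied fragment numbers gave -0.23. Those numbers come from the same estimates as the FPKM, so they cannot decide whether transcript models that differ between the assemblies play a part. Loss of long transcripts in the fat-tailed library cannot be told apart from other sources. Within deciles of span the correlation of the ratio with implied transcript length had a median of -0.037 and ranged from -0.11 to 0.18. Within deciles of implied length the correlation of the ratio with span had a median of -0.12. Implied length is approximate, so a correlation with span could remain within its deciles in either case. GC content was not tested, since no genome was used, and the tail types remain an untested explanation.

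Among matched loci there were 1.77 lower calls per higher call in the fat-tailed library. The lowest 3 deciles of mean level held 327 higher and 904 lower loci, against 762 and 1028 in the others. With a matching overlap of 50% there were 1.56 lower calls per higher call, and with 95% there were 1.81. The full tables listed more loci with FPKM of at least 1 in the fat-tailed library, 19865 against 19168. Loss of loci in the matching was not tested as a source of the uneven calls. Sampling noise as the source is argued against by the 1.499 that remained with FPKM of at least 5 in 1 library, and by the 3.35 among loci of the lowest 3 deciles of level above 0 in both libraries whose intervals did not overlap. A scaling offset stays open: centring on loci with at least 1 FPKM in both libraries left 1.44, and centring all compared loci left 1.23, between the bounds set for that test. Removing the span trend while keeping the median of all loci left 1.78, and removing both left 1.225 against 1.232 for the offset alone. The figure was 1.098 in the shortest 3 deciles of span and 2.60 in the longest 3, so trend and offset cannot be told apart, since the median of all loci holds both, and a difference between the tail types was not tested.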
